A study of Mus musculus with 24 samples.

How the data were processed

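Gene expression was measured in amygdala and hippocampus of male mice (Mus musculus) from 2 lines bred for freezing in contextual fear conditioning, a test in which mice are placed back in a chamber where they had received foot shocks and the time spent motionless is scored. Per the labels, line 24 is the low freezing line and line 25 the high freezing line. The 24 Affymetrix arrays fall into 4 groups of 6: amygdala and hippocampus of the low line (arrays 1 to 6 of each tissue) and of the high line (arrays 7 to 12 of each tissue). Groups were taken from the sample descriptions, and array numbers from the sample titles. The labels do not say whether an array number marks the same animal in both tissues, nor whether RNA was pooled. Each line is a single breeding line here, so the p-values measure the spread between arrays within these lines, and a difference that selection made cannot be separated from one that arose by drift between the lines.

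The values the authors deposited are linear intensities, 1 per probe set (a set of probes that reads 1 transcript or part of it). The signal algorithm, its software and the handling of the tissue are not given in the sources used here. From the values, each array had been scaled so that its mean without the highest and lowest 2% of the probe sets is 150, while the quartiles were not made equal. The array medians ran from 43.3 to 55.7. No column of values was left unmapped. An array gives no count of molecules, so the precision of a group mean rests on the number of arrays and the spread between them.

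Of the 45101 probe sets, 64 controls were left out and 45037 were tested. Names came from the platform annotation: 34945 probe sets carry 1 gene symbol, 932 several and 9160 none. Through the Entrez identifier, 34741 of the first were given the symbol of the GRCm38.p6 reference table, and together they name 18193 genes. Probe sets with several symbols or none were tested and counted but given no gene name. The values file names no genome build, so no coordinates are given, and the reference table served only for names and for the order of 18140 genes along the chromosomes.

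Signals were tested as log2(value + 16). Differences on this scale understate the change of weakly expressed genes. The line difference, high minus low, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the 12 arrays of a tissue alone, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between tissues, and the difference of the line effect between tissues, were contrasts in a fit of the 4 group means over all 24 arrays. For each gene the probe set with the highest mean stood for it in tests of gene lists. The 38 lists, covering regional markers, markers of other cell types, transmitter and peptide receptors, stress and memory pathways, channels and cell state, were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Camera asks whether a list moved relative to all other genes. Fry asks whether its members moved, on balance, in 1 direction, and its mixed test whether they changed in either direction. A list of sex-linked genes was a label check only.

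The lists, the tests and the rule for naming genes were fixed before the data were examined. Genes are named from probe sets with 1 symbol, and symbols that are clone or gene-model names are counted but not named, except where a count of 5 or fewer asks for them. In each tissue up to 10 called genes per direction are named by fold change, each with its called probe set of lowest p. Where fewer than 5 genes were called, the 10 with the lowest p are named as values that did not pass. For both tissues, up to 10 genes called in both were to be named, by the smaller of their differences; none was called in both. Up to 10 called genes by lowest p were to be named for the difference between tissues of the line effect; none was called. Up to 8 genes per direction are named for the tissue comparison, with up to 4 regional markers. A list shows up to 4 called members, or up to 2 members of lowest p as values. The 20 genes named for both tissues at an unadjusted p under 0.01, further list members past the threshold over the list alone, the 2 genes given for the difference between tissues, the clone and gene-model names, and the neighbouring pairs, were chosen after the data were seen.

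The fits were tested on simulated arrays that kept the mean and the within-group SD of each of the 45037 probe sets, with 50 probe sets changed by each of 4 known amounts, drawn from those above the median signal, so that the shares say nothing about weaker probe sets. The simulated spread was equal in both lines, and many changed probe sets in 1 fit loosen the adjusted threshold. The shares can therefore overstate recovery in the real line tests, which called 10 probe sets in hippocampus and 1 in amygdala. In hippocampus the line test recovered 50% of the 50 probe sets changed by 0.5 on the log2 scale, 86% of those changed by 1, 98% at 1.5 and 98% at 2. In amygdala these shares were 44%, 92%, 100% and 96%, for the tissue comparison 80%, 100%, 100% and 100%, and for the difference of the line effect between tissues 36%, 86%, 100% and 100%. False calls numbered 12, 12, 11 and 9 in hippocampus, amygdala, the tissue comparison and the difference between tissues. A camera list of 30 genes raised by 0.3 was recovered in each tissue with no false call among 30 unchanged lists. The simulated arrays carry no correlation between genes, so this says nothing about false calls of lists on the real arrays.

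Alternatives were quantile normalization, median centring, leaving out the lowest 40% of probe sets, other constants in the logarithm (1 and 64), an intensity trend or array weights in limma, a fit of all 24 arrays, 1 probe set per gene, the array number as a block, other gene-list tests and each array left out in turn. Alternatives without arrays of doubtful quality, or with Ttr as a covariate, were added after the data were seen. Each count was also set against 100 splits of the arrays, drawn with a fixed seed. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.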

Results

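Amygdala and hippocampus of male mice from a line bred for low freezing (line 24) and a line bred for high freezing (line 25) were profiled on 24 arrays, 6 per line and tissue. The title of the series names selection for contextual fear conditioning and its effect on gene expression, so the first question is which transcripts differ between the lines in each tissue. Values are log2(signal + 16) with SD over 6 arrays per group unless stated otherwise, and differences are high line minus low line. Array medians were between 43.3 and 55.7 in linear signal. Across probe sets, arrays of the same group correlated at 0.953 to 0.979 and arrays of different tissues at 0.936 to 0.966. Xist, the transcript of the inactive X chromosome, stayed between 4.83 and 6.08 on all 24 arrays, below a level of 8. Of the Y-linked genes, Eif2s3y lay between 7.67 and 8.50, above 8 on 15 of the 24 arrays, while Uty (6.01 to 6.76) and Kdm5d (up to 7.07) were above 8 on 0. The low Xist goes with the male label, and without female arrays the level of the Y-linked genes decides nothing.

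Amygdala and hippocampus were separated by large, regionally known transcripts. Penk, which encodes the enkephalin precursor, was 11.9-fold higher in amygdala (11.50 ± 0.25 against 7.93 ± 0.21, SD, n = 12 arrays per tissue, adjusted p = 2.43e-18). Also higher in amygdala were Baiap3 (7.15-fold), the dopamine receptor gene Drd1 (6.78-fold), the transcription factor gene Foxp2 (6.66-fold), Gpr6 (6.62-fold), the glycine receptor subunit gene Glra3 (6.60-fold), Ppp1r1b, the dopamine-regulated phosphatase inhibitor of striatal neurons (5.39-fold), and neuroglobin, Ngb (5.34-fold). Dsp, the desmosome protein desmoplakin, was 14.3-fold higher in hippocampus (8.63 ± 0.25 against 4.80 ± 0.24, n = 12, adjusted p = 5.11e-20), followed by Lct (11.8-fold), Lefty1 (7.24-fold), the calcium-binding protein gene Cabp7 (5.76-fold), C1ql2 (5.39-fold), the neuronal transcription factor gene Pou3f1 (5.02-fold), Ccbe1 (4.79-fold) and the neuronal calcium sensor hippocalcin, Hpca (4.52-fold).

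Regional markers fixed in advance followed the labels for the most part. Of 24 measured hippocampus markers 22 were called higher in hippocampus and 1 higher in amygdala, among them Zbtb20 (3.42-fold higher in hippocampus) and Pkp2 (4.30-fold). Of 23 amygdala markers 16 were called higher in amygdala and 3 higher in hippocampus, with Meis2 (4.17-fold) and Nr2f2 (2.51-fold) among the lowest p. The counts adjusted over the list alone were the same for both lists. All 14 striatum markers were also higher in amygdala samples. In all, 11615 of 45037 probe sets were called between the tissues, 5823 higher in amygdala and 5792 higher in hippocampus. The control probe set for the 5' end of 18S ribosomal RNA read 295 to 1525 in linear signal on the amygdala arrays and 3600 to 7093 on the hippocampus arrays, so that tissue and RNA or label preparation cannot be told apart in this comparison.

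In hippocampus 6 named genes differed between the lines, 1 higher and 5 lower in the high freezing line. Cd99l2, which encodes a cell-surface adhesion protein of the CD99 family, had the largest difference: it fell from 8.27 ± 0.08 to 6.35 ± 0.70 (n = 6 arrays per line, difference -1.92 ± 0.26 SE, adjusted p = 0.0339). Mrps15, a protein of the mitochondrial ribosome, fell by 1.16 (SE 0.14, adjusted p = 0.0264), and Ppp2r5c, a regulatory subunit of protein phosphatase PP2A, fell by 0.97 (SE 0.13, adjusted p = 0.0339). Prpf19, a ubiquitin ligase of the pre-mRNA splicing machinery, fell by 0.74 on each of 2 called probe sets (adjusted p = 0.0264 and 0.0301), and Armh4 fell by 0.71 (SE 0.09, adjusted p = 0.0339). Pde1c, a calcium- and calmodulin-dependent phosphodiesterase that breaks down cyclic nucleotides, rose from 5.38 ± 0.19 to 6.12 ± 0.13 (difference 0.74 ± 0.10 SE, adjusted p = 0.0339).

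**Figure D1:**
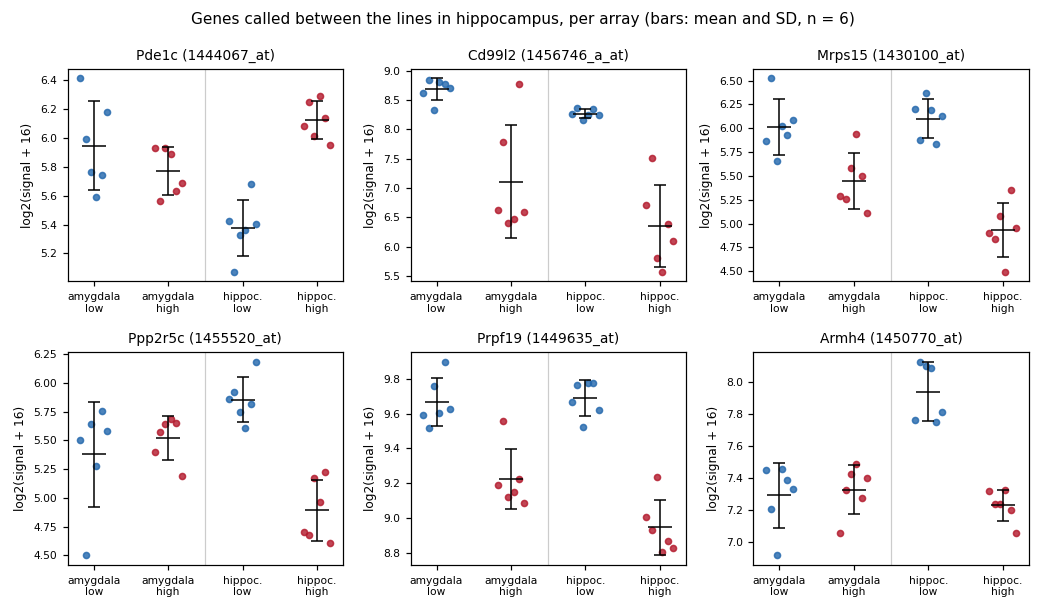
Log2(signal + 16) of the 6 named genes called in hippocampus, 1 point per array, for the 2 lines in amygdala and hippocampus; bars are mean and SD of 6 arrays. In hippocampus the 2 lines do not overlap for any of the 6 genes, while in amygdala they overlap for each of the 6, Cd99l2 included at 8.68 ± 0.19 in the low and 7.11 ± 0.96 in the high line. Cd99l2, Mrps15 and Prpf19 were also lower in amygdala of the high line, at an unadjusted p under 0.01 (-1.58, -0.57 and -0.44). Pde1c, Ppp2r5c and Armh4 were not past that p there (-0.18, 0.14 and 0.04).

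The other hippocampus calls were 1700029H14Rik (1.25 higher), Gm29514 (difference -0.98) and a probe set without a gene name (1.08 higher), which makes 10 called probe sets, 3 higher and 7 lower. The arrays of the lines did not overlap for any of the 10, which choosing probe sets by p all but ensures. Over all probe sets, 287 (0.637%) had no overlap, where chance gives 0.216%. The 18S ribosomal RNA 5' control, a reading of RNA or label preparation, did not overlap between the hippocampus lines either (5859 to 7093 in the low and 3600 to 5799.9 in the high line), so preparation and line cannot be told apart for these calls or for the hippocampus lists. The other probe sets of the same genes shared the difference only in part. Of 20 other probe sets, 5 moved the same way at an unadjusted p under 0.05: 2 of 5 for Pde1c, 2 of 3 for Cd99l2 and 1 of 4 for Prpf19, against 0 of 2 for Mrps15 and 0 of 6 for Ppp2r5c, and Armh4 had none. The 1 for Prpf19 is itself among the 10 calls, and its probe sets with mean signals of 11.79 and 8.80 lay at -0.002 and 0.006. The called probe sets of Mrps15 and Ppp2r5c had low signals, 6.10 and 5.85 in hippocampus of the low line. Brighter probe sets of Mrps15, with mean signals of 8.11 and 8.49, lay at -0.06 and -0.04 in hippocampus. The brightest of Ppp2r5c, with mean signals of 10, 9.26 and 9.20, lay at -0.10, 0.13 and -0.12. The 2 for Pde1c had low mean signals, 4.42 and 4.65. Its other probe sets lay at 0.39, -0.28 and -0.24, with -0.28 on the brightest (mean 6.21). The remaining probe set of Cd99l2 had the opposite sign, 0.36 in amygdala and 0.18 in hippocampus. At an unadjusted p under 0.05 there were 4040 probe sets, where other splits of the arrays gave a median of 2057 and up to 3991. Hippocampus array 7, of the high line, scored 80.7 on the first principal component of its tissue (19.7% of the variance), the others between -29.3 and 33.0, and had the highest median signal, 55.7. Without it 14 probe sets were called, 8 of the 10 among them, and 5 lists passed. The limma count was 0 without array 1, 2, 3, 4, 6 or 12, 1 without array 8 or 11, and 4 without array 5 or 10. It was 0 with log2(value + 1), 20 without the lowest 40% of probe sets (6 of the 10 among them), 26 with log2(value + 64), 51 in a fit of all 24 arrays and 57 with an intensity trend. Quantile normalization also called 10, but 1 higher and 9 lower, and median centring 12, 1 higher and 11 lower.

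Genes that mark the hippocampus had mostly lower signals in hippocampus of the high freezing line. The number of hippocampus lists past the camera threshold, 5 of 38, was also reached by other splits of the arrays, with a median of 2 and the highest at 6, and the 18S control separated the same arrays. Of 24 such markers 18 had a negative difference (median -0.08, camera adjusted p = 5.00e-05; adjusted p = 0.363 with an estimated correlation). When adjusted over the list alone 6 fell, while 0 were called over all genes. C1ql2, a secreted C1q-like synaptic protein, had the largest difference of them, at -0.94 ± 0.15 SE (8.42 ± 0.32 in the low and 7.48 ± 0.19 in the high line, adjusted p = 0.0754 over all genes and 6.80e-04 over the list alone). Dsp was at -0.36 ± 0.11 SE, Lct at -0.34 ± 0.10 SE, Spink8 at -0.32 ± 0.09 SE and Hpca at -0.23 ± 0.06 SE.

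Genes of energy metabolism and of protein synthesis had small negative differences in hippocampus. Of 59 oxidative phosphorylation genes 47 had a negative difference (median -0.05, camera adjusted p = 3.28e-05), and so had 37 of 43 cytosolic ribosomal protein genes (median -0.06, camera adjusted p = 5.00e-05). The adjusted p values with an estimated correlation were 0.426 and 0.363, and with quantile normalization neither list passed (list: oxidative phosphorylation, hippocampus, 0.269; list: cytosolic ribosomal proteins, hippocampus, 0.176). No member passed over all genes or over the list alone, and the lowest p belonged to Ndufb8, a complex I subunit, at -0.21 ± 0.07 SE and to Rps18, a small-subunit ribosomal protein, at -0.19 ± 0.06 SE. The 5' signal of the 18S ribosomal RNA control, a reading of RNA or label preparation, was lower in hippocampus of the high line, 5195 ± 882 against 6702 ± 501 in linear signal (exact permutation test, two-sided p = 0.00216, Benjamini-Hochberg adjusted 0.0346 over 16 array measures). Preparation and line therefore cannot be told apart for these lists.

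Markers of meningeal fibroblasts and of microglia had mostly higher signals in hippocampus of the high line, whose arrays also had the lower 18S control. Of 14 fibroblast and meninges markers 13 had a positive difference (median 0.23, camera adjusted p = 2.73e-04; adjusted p = 0.363 with an estimated correlation). Over the list alone 2 were higher, Mgp, the matrix Gla protein, at 0.42 ± 0.10 SE and Fmod, fibromodulin, at 0.50 ± 0.15 SE, where the other 5 probe sets of Fmod lay between -0.07 and 0.19. Of 20 microglia and macrophage markers 16 had a positive difference (median 0.11, camera adjusted p = 0.0212, and adjusted p = 0.363 with an estimated correlation). Over the list alone 1 was higher, C1qb, a chain of complement C1q, at 0.53 ± 0.13 SE, while C1qc was at 0.46 ± 0.15 SE and C1qa at -0.19 ± 0.09 SE. Neither list passed when all probe sets of a gene were averaged (list: fibroblast and meninges markers, hippocampus, 0.0541; list: microglia and macrophage markers, hippocampus, 0.0588). By fry 0 of the 38 lists had a balance in 1 direction (lowest adjusted p = 0.0623), while 10 lists passed its mixed test of change in either direction: the 5 that passed camera, plasticity kinases and CREB signalling, endocannabinoid signalling, GABA receptors and GABA handling, serotonin signalling, and cortex and claustrum markers. The count for the mixed test was not set against other splits of the arrays.

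**Figure D2:**
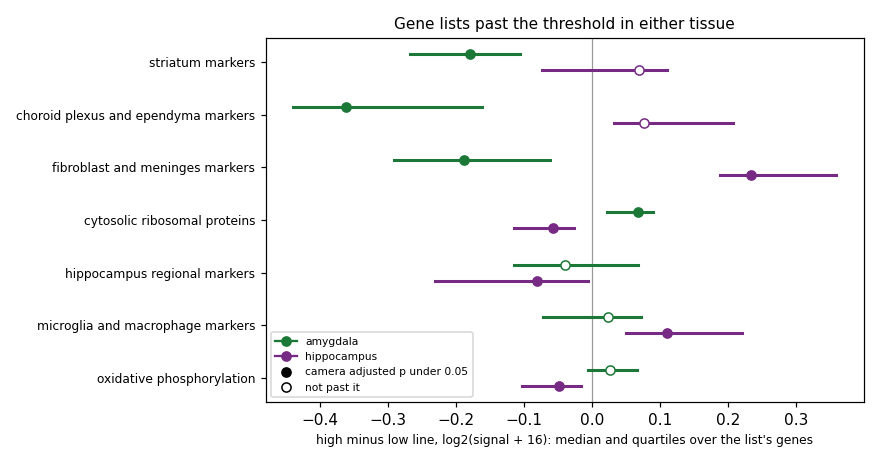
Median (point) and quartiles (bar) of the line difference, high minus low, in log2(signal + 16) over the genes of each list that passed camera in either tissue; filled points are past an adjusted p of 0.05 in that tissue. The fibroblast and meninges list lies at -0.19 in amygdala and 0.23 in hippocampus, and no list passes with an estimated correlation.

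The lists tied most directly to fear learning and stress did not move as a whole relative to other genes in hippocampus, as camera tests it. Fry's mixed test of the list as a whole, in either direction, passed for 4 of them, in which no member passed over all genes or over the list alone: plasticity kinases and CREB signalling (adjusted p = 0.00266), endocannabinoid signalling (0.00426), GABA receptors and GABA handling (0.00791) and serotonin signalling (0.0284). The mixed test does not compare a list with other genes. At an unadjusted p under 0.05 lay 2 of 34, 2 of 12, 1 of 16 and 5 of 17 of their members, in that order, and 4040 of all 45037 probe sets. By camera, none passed. Plasticity kinases and CREB signalling came nearest in camera (median -0.03, adjusted p = 0.0742), with Nrgn, neurogranin, at -0.20 ± 0.07 SE and Camkk2 at -0.18 ± 0.07 SE. Immediate early genes (adjusted p = 0.986), neurotrophins and their receptors (0.770), corticotropin and glucocorticoid signalling (0.770), endocannabinoid signalling (0.770), GABA receptors and GABA handling (0.943), ionotropic glutamate receptors and partners (0.734), metabotropic glutamate receptors and glutamate transport (0.950), serotonin signalling (0.770), dopamine and noradrenaline signalling (0.943), acetylcholine signalling (0.853), and neuropeptides and their receptors (0.976) had higher p in camera. The lowest p values in the endocannabinoid and serotonin lists belonged to Ptgs2, a cyclooxygenase, at -0.48 ± 0.15 SE, and to Tph2, the brain enzyme that starts serotonin synthesis, at -0.47 ± 0.15 SE, followed by the serotonin transporter gene Slc6a4 at 0.47 ± 0.19 SE. None of the 3 passed over the list alone. Tph2 and Slc6a4 had low signals in hippocampus. Tph2 read 5.04 in the low and 4.57 in the high line, and Slc6a4 4.30 and 4.77.

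Synaptic vesicle and release machinery (0.770), potassium channels (0.853), calcium and sodium channels (0.853), glyoxalase and antioxidant enzymes (0.770), heat shock and protein folding (0.976), the circadian clock (0.770), interferon response and antigen presentation (0.943), and genes known to differ among inbred strains (0.755) did not pass either. Among regional and cell type lists, hypothalamus (0.205), oligodendrocyte and myelin (0.463), oligodendrocyte precursor (0.734), interneuron (0.734), immature neuron and neurogenesis (0.755), amygdala (0.770), thalamus and habenula (0.770), cortex and claustrum (0.770), choroid plexus and ependyma (0.770), astrocyte (0.770), striatum (0.853), red blood cell (0.853), and endothelial and pericyte markers (0.968) did not pass camera, with cortex and claustrum markers at an adjusted p of 0.0457 in fry's mixed test. Adjusted over the list alone, 1 member each was higher among amygdala markers (Lypd1, 0.61 ± 0.14 SE), cortex and claustrum markers (Ccn2, 0.45 ± 0.10 SE) and red blood cell markers (Car1, 0.73 ± 0.22 SE). Car1 had low signals, 4.60 in the low and 5.33 in the high line.

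In amygdala no gene with a name was called between the lines. The only call, a probe set that names no gene, was lower in the high line, at 4.36 ± 0.08 against 5.26 ± 0.23 (difference -0.90 ± 0.10 SE, adjusted p = 0.0385). The 10 genes with the lowest p did not pass, at adjusted p of 0.257 to 0.302. With positive differences these were Scmh1 (1.37 ± 0.24 SE), Ece1, the endothelin-converting enzyme (1.05 ± 0.15 SE), Glra1, a glycine receptor subunit (0.73 ± 0.13 SE), C1qc (0.68 ± 0.12 SE), Lypd1, a Ly6-family protein that binds nicotinic acetylcholine receptors (0.51 ± 0.08 SE), and the cytokine gene Il17d (0.51 ± 0.09 SE). With negative differences they were Tnnt2, a cardiac troponin (-1.33 ± 0.24 SE), Fut10 (-0.92 ± 0.14 SE), Ppt1, a lysosomal palmitoyl-protein thioesterase (-0.47 ± 0.08 SE), and Med25, a Mediator subunit (-0.35 ± 0.06 SE). The other probe set of Lypd1 had the opposite sign in amygdala (-0.60 against 0.51), as had 1 of the 2 other probe sets of Ece1 (-0.35 against 1.05). At an unadjusted p under 0.05 limma gave 2945 probe sets, where other splits of the arrays gave a median of 2128 and up to 3101. Amygdala arrays 7 and 8, both of the high line, had actin 5' to 3' ratios of 0.301 and 0.339, below the 0.497 to 0.630 of the other 10, and without them the count was 0. The count was also 0 without array 2, 4, 5, 7, 8, 9, 10 or 12, without the lowest 40% of probe sets, with log2(value + 64) and with an intensity trend. It was 2 without array 1, 3 without array 6 or 11, and 6 in a fit of all 24 arrays.

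Markers of striatum, choroid plexus and meninges had mostly lower signals in amygdala samples of the high line. The number of amygdala lists past the camera threshold, 4 of 38, was also reached by other splits of the arrays, with a median of 3 and the highest at 7. With an estimated correlation the adjusted p of each of the 4 was 0.962. All 14 striatum markers had a negative difference (median -0.18, camera adjusted p = 0.0259), the lowest p belonging to Pde10a, the phosphodiesterase of striatal projection neurons, at -0.30 ± 0.15 SE and to Ido1 at -0.36 ± 0.19 SE. Of 19 choroid plexus and ependyma markers 18 were negative (median -0.36, camera adjusted p = 0.0259), with Slc4a5 at -0.44 ± 0.29 SE and Igf2 at -0.38 ± 0.26 SE, and of 14 fibroblast and meninges markers 12 were negative (median -0.19, camera adjusted p = 0.0433), with Slc22a6 at -0.61 ± 0.23 SE. Of 43 cytosolic ribosomal protein genes 35 were positive (median 0.07, camera adjusted p = 0.0433), with Rpl37a at 0.13 ± 0.08 SE and Rpl37 at -0.17 ± 0.09 SE. No member of these lists passed over all genes or over the list alone. By fry the lowest adjusted p over the 38 lists was 0.763, and 0.119 in its mixed test. Without amygdala arrays 7 and 8, the high line arrays with low actin ratios, 2 of the 4 lists were past the threshold, and with Ttr as a covariate 1. The count of 4 lists fell to 2 with quantile normalization, which the ribosomal and the fibroblast lists did not pass. It was 0 without array 1, 6 or 12, 1 without array 3, 8 or 11, 2 without array 4, 5 or 9 and 0 when all probe sets of a gene were averaged.

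The receptor, stress and memory lists did not pass in amygdala. Adjusted p was 0.413 for dopamine and noradrenaline signalling and for synaptic vesicle and release machinery, 0.434 for metabotropic glutamate receptors and glutamate transport, 0.612 for GABA receptors and for serotonin signalling, 0.648 for neuropeptides and for potassium channels, 0.674 for immediate early genes, 0.718 for ionotropic glutamate receptors, 0.835 for plasticity kinases and for calcium and sodium channels, 0.862 for corticotropin and glucocorticoid signalling, 0.938 for endocannabinoid signalling, 0.953 for acetylcholine signalling and 0.976 for neurotrophins. The lowest p among their members belonged to Slc18a2, the vesicular monoamine transporter, at -0.44 ± 0.15 SE. Astrocyte markers (0.311), oxidative phosphorylation (0.319), glyoxalase and antioxidant enzymes (0.469) and heat shock and protein folding (0.542) did not pass, nor did the remaining cell type, regional and cell state lists (0.612 to 0.976). Over the list alone Lypd1 was higher among 23 amygdala markers by its probe set of highest signal, its other probe set being lower (-0.60), C1qc was higher among 20 microglia markers, Pkp2 was lower among 24 hippocampus markers (-0.40 ± 0.09 SE) and Alas2, the heme synthesis enzyme of red cells, was lower among 6 red blood cell markers (-0.86 ± 0.18 SE). Alas2 had low signals, 5.55 in the low and 4.69 in the high line.

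No probe set was called for a line difference that itself differed between the tissues. The lowest adjusted p in limma was 0.156, for a probe set without a gene name, and 3189 probe sets had an unadjusted p under 0.05, where other splits gave a median of 1917 and up to 4003. Among named genes Pde1c (difference -0.18 ± 0.14 SE in amygdala and 0.74 ± 0.10 SE in hippocampus) and Armh4 (0.04 ± 0.11 SE and -0.71 ± 0.09 SE) had the lowest p, each at an adjusted p of 0.260. The hippocampus calls are therefore not shown to be absent in amygdala. The count was 1 without array number 1 or 11.

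Across tissues, no probe set was called in both. The line differences of the 45037 probe sets correlated at r = 0.0836 between amygdala and hippocampus (jackknife SE 0.0529 over array numbers), a value across probe sets, which are not independent replicates. Without the lowest 40% of probe sets it was 0.184, and between odd-numbered arrays of amygdala and even-numbered arrays of hippocampus 0.0586, with 0.0345 for the reverse. Counted after the data were seen, 80 probe sets had an unadjusted p under 0.01 in both tissues, and 72 of them had the same direction (35 higher and 37 lower), where independent lists give 8.13.

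Some of these shared differences were large. Prune2 had a difference of -3.04 ± 0.56 SE in amygdala (9.58 ± 0.73 in the low and 6.54 ± 1.37 in the high line) and of -2.84 ± 0.61 SE in hippocampus, and Cd99l2 of -1.58 ± 0.36 SE and -1.92 ± 0.26 SE. Cap1, a cyclase-associated actin regulator, had differences of -1.67 ± 0.35 SE and -0.92 ± 0.14 SE, and Atxn1, ataxin, of -1.23 ± 0.24 SE and -1.13 ± 0.26 SE. Rpgrip1, a photoreceptor cilium protein, was higher by 1.53 and 1.88, Efhd2, a calcium-binding EF-hand protein, by 1.12 and 1.25, and Pam, the enzyme that amidates neuropeptides, by 1.13 and 1.02. Rgcc was higher by 1.54 in hippocampus and at 9.04 ± 0.30 against 7.53 ± 0.89 in amygdala. Lower in both were also Ptp4a2, the replication helicase subunit gene Mcm6, Pigt, Hps1, Urgcp, the G protein subunit gene Gnb1, Fut10 and Nav1, with differences of -0.92 to -0.66, and higher were Morn1, Mzt1, Smim10l1 and Ang, angiogenin, with differences of 0.69 to 1.42. Fut10 was read here by a different probe set from the one named for amygdala, which lay at -0.06 in hippocampus. Its remaining probe set lay at 0.14 in amygdala and 0.03 in hippocampus. Apart from Cd99l2 in hippocampus, none of these 20 genes passed the adjusted threshold in either tissue.

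**Figure D3:**
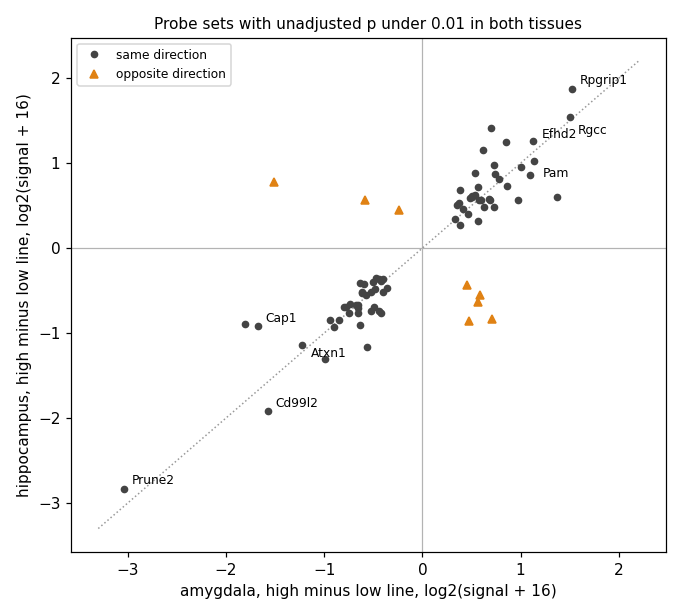
Line difference, high minus low, in log2(signal + 16) in amygdala (x axis) and hippocampus (y axis) for the 80 probe sets with an unadjusted p under 0.01 in both tissues; the dotted line marks equal differences. The 72 dots have the same direction, the 8 triangles opposite ones, and Prune2 lies farthest out at -3.04 and -2.84.

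For 5 of the 20 genes another probe set shared the direction in both tissues at an unadjusted p under 0.05 (Cd99l2, Cap1, Mcm6, Ang and Nav1), and for Prune2 and Ptp4a2 another probe set had the opposite direction in both. Of 47 other probe sets 6 shared and 2 opposed. Signals were often uniform in only 1 line: the SD over both tissues was more than 2 times larger in the low line for 6 of the 20 genes, as for Rpgrip1 (1.03 against 0.120), and in the high line for 6, as for Cd99l2 (0.842 against 0.144). In 19 of the 20 the line with the lower signal had the larger SD.

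None of the 8 called hippocampus genes that could be placed in gene order lay next to another, and amygdala had no called gene to place. Random sets of 8 genes gave 0.0017 pairs on average, so a count of 0 decides nothing. In the set of 53 genes with the same difference in both tissues, chosen after the data were seen, 3 pairs were direct neighbours among 18140 ordered genes, where 10000 random sets of as many genes gave 0.146 on average (permutation of the gene set, one-sided p = 8e-04). These were Khdrbs1 with Ptp4a2 and Rpgrip1 with Supt16, each pair with opposite directions, and Il17d with Eef1akmt1, both higher. Within 10 genes there were 10 pairs against 1.48 on average (permutation of the gene set, one-sided p = 1e-04, the smallest the random sets can give), among them Slc35f5 with Lypd1, Morn1 with Gnb1, Vps37c with Prpf19, and Golga7b with Hps1. The 755 genes at an unadjusted p under 0.01 in hippocampus held 46 direct neighbour pairs against 31.3 (same permutation, one-sided p = 0.0067). For the 512 such genes in amygdala there were 21 against 14.4 (same permutation, p = 0.054).

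Choroid plexus transcripts varied widely between arrays in both lines. Ttr, transthyretin, the main secreted protein of the choroid plexus, spanned 8.92 to 13.69 in amygdala, a 27.2-fold range, and 10.39 to 13.95 in hippocampus, an 11.8-fold range. Its mean was 12.67 ± 1.27 in the low and 12.06 ± 1.90 in the high line in amygdala (n = 6 each, exact permutation test, two-sided p = 0.582), and 12.95 ± 1.36 and 12.87 ± 1.26 in hippocampus (exact permutation test, p = 0.894). Over the 12 arrays of a tissue Ttr followed the mean of the 18 other choroid plexus and ependyma markers, with r = 0.864 and rho = 0.951 in amygdala (permutation p = 3e-05 and 1e-05, the latter the smallest possible; 6e-05 and 2e-05 adjusted over 2 tissues) and r = 0.837 and rho = 0.888 in hippocampus (permutation p = 1e-04 and 2e-04, adjusted 1e-04 and 2e-04). Without the 2 arrays farthest from the median of Ttr, r was 0.891 and 0.799. Within the lines, 6 arrays each, r was 0.906 (low) and 0.886 (high) in amygdala and 0.781 and 0.910 in hippocampus. With Ttr as a covariate, 5 probe sets were called between the lines in hippocampus and 1 in amygdala, and the amygdala lists past the threshold fell from 4 to 1.

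**Figure D4:**
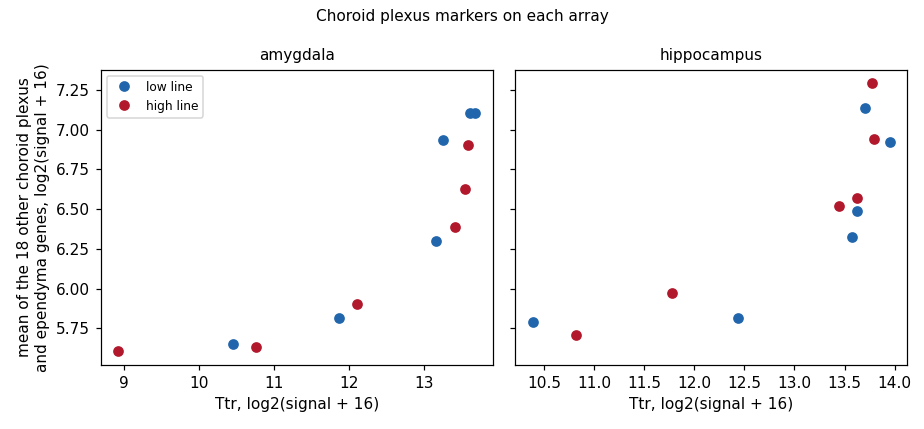
Ttr (x axis) against the mean of the 18 other choroid plexus and ependyma markers (y axis), both in log2(signal + 16), 1 point per array, in amygdala and hippocampus with the lines in colour. Low and high line arrays are found at both ends in each tissue, with Ttr from 8.92 to 13.69 in amygdala and from 10.39 to 13.95 in hippocampus.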

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

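Among the groups of 6 arrays behind the genes named for the line comparisons, 8 of 118 held 1 array far from the other 5, where chance gives about 1 in 20. The genes named for both tissues among them were chosen after the data were seen. For Tnnt2, array 11 of the amygdala high line read 5.57, while the other 5 lay between 4.14 and 4.46. Prune2 read 8.16 on array 4 of the amygdala low line, with the others at 9.498 to 10.15. On array 7 of the amygdala high line Cap1 read 6.74 against 8.51 to 9.26, and Rpgrip1 10.39 against 10.56 to 10.65. Rgcc read 8.50 on array 7 of the hippocampus high line against 9.29 to 9.59, and Smim10l1 10.42 on array 10 of that group against 9.31 to 9.5. Fut10 stood apart on the same probe set in both tissues, at 5.73 on array 2 of the amygdala low line against 5.14 to 5.29 and at 4.34 on array 4 of the hippocampus low line against 5.20 to 5.52. Of 32 groups for array-wide measures 1 held such an array: the first principal component of amygdala placed array 2 of the low line at -46.9, with the others of that line between -11.1 and 1.28. On the same component the high line arrays of low actin ratio, 7 and 8, lay at 47.8 and 31.5. The other high line arrays lay between -4.69 and 0.203.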

How the results depend on the processing

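The alternatives without doubtful arrays, with Ttr as a covariate, and those for probe sets with the same difference in both tissues were chosen after the data were seen. No named gene or list changed direction under any alternative run for it, all 16 tissue genes kept their calls in 256 of 256 values, and the 9 hippocampus calls followed individually lost their call in 110 of 197 values. Pde1c, the only named gene called higher, lost its call most often (17 of 22). The 20 genes named for both tissues no longer had an unadjusted p under 0.01 in both in 98 of 337 values, most often Pigt (15 of 17) and Smim10l1 (14 of 17). The 9 lists fell short of the threshold in 67 of 162 values.

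Amygdala, with 1 called probe set, gave 0 without the lowest 40% of probe sets, 0 with log2(value + 64), 0 with an intensity trend, 0 with 1 probe set per gene symbol (where the called probe set, which has no symbol, was not tested), 0 without the 2 arrays of low actin ratio, and 6 in 1 fit of all 24 arrays, with 0 to 3 over arrays left out. Hippocampus, with 10, gave 20 without the lowest 40%, 0 with log2(value + 1), 26 with log2(value + 64), 51 in the fit of all 24 arrays, 57 with an intensity trend, 4 with 1 probe set per gene symbol (fewer probe sets tested) and 5 with Ttr as a covariate, with 0 to 14 over arrays left out; of the 10, 9 were among the 57, 10 among the 51, 10 among the 26 and 6 among the 20, and 8 were among the calls with quantile normalization and 8 among those without array 7. The cause of these changes was not tested. The fit of all 24 arrays treats both tissues as independent and has more residual degrees of freedom.

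The array number was tried as a replicate block. Over all probe sets the residuals of same-numbered arrays correlated at -0.0545 to 0.0454 (0 of 12 above 0.1). No other pair of arrays lay above 0.1 either, with different lines at -0.0513 to 0.0618. These values therefore cannot tell whether a number marks an animal. Only 1 of 12 amygdala arrays had its closest hippocampus array under its own number in the 34 variable genes described under the other observations. With the replicate block the called probe sets, amygdala against hippocampus, numbered 10703, against 11615 without, and 0 for the difference of the line effect between tissues, against 0. Over array numbers left out, the tissue count ran from 10435 to 11180 and the other from 0 to 1.

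The count called in both tissues was 0 in every alternative run and in each leave-out (0 to 0). The correlation of line differences was 0.0836 with a jackknife SE of 0.0529, 0.184 without the lowest 40%, and 0.0548 to 0.106 over numbers left out. The 72 probe sets with the same difference became 18 and 18 with odd against even array numbers, 46 without amygdala arrays 7 and 8 and hippocampus array 7, and 52 to 76 over numbers left out, where fewer arrays enter. The 4 amygdala lists became 0 with an estimated correlation, 0 with fry, 0 with the mean of all probe sets, 2 with quantile normalization, 2 without the 2 arrays of low actin ratio and 1 with Ttr as a covariate (0 to 4 over arrays left out). The 5 hippocampus lists became 0 with an estimated correlation, 0 with fry, 3 with the mean of all probe sets and 3 with quantile normalization (4 to 7 over arrays left out). Neighbouring pairs numbered 0 among the 8 placed hippocampus calls and 3 among the 53 genes at an unadjusted p under 0.01 in both tissues, sets of unlike size. At an adjusted p under 0.01 there were 0 hippocampus genes, so no value could be had. Between 22.9% and 28.8% of the probe sets of an array read below 16, where log2(value + 16) compresses differences.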

Other observations

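The tests on probe sets with the same difference in both tissues (except the one on other probe sets), and both tests on matching arrays, were chosen after the result was seen. Of other groups, oligodendrocyte and myelin markers were higher in hippocampus than in amygdala samples (11 of 18 called, 0 the other way, 7 not called), as were 10 of 19 astrocyte markers against 4 higher in amygdala. Interneuron markers were higher in amygdala for 11 of 19 and in hippocampus for 4, and 6 of 20 microglia and macrophage markers were higher in amygdala with 0 in hippocampus. Cortex and claustrum markers were higher in amygdala for 9 of 16 and in hippocampus for 3, thalamus and habenula markers for 3 and 1 of 17. Red blood cell markers differed for 0 of 6 measured of 12 listed, and choroid plexus and ependyma markers for 1 of 19, higher in hippocampus. The globin genes among the former had low signals, with group means of 4.34 to 4.58 for Hba-a1 and 5.23 to 5.44 for Hbb-b2. The count of 0 therefore cannot rule out a difference in blood content.

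Set against 100 splits of the arrays, the real one included, the 10 hippocampus calls (1 split as large, the highest other 3) and the 11615 calls between tissues (1 split, highest other 3479) stood apart. A share of 1 in 100 is the smallest these splits can give, so chance is made unlikely there but not excluded. The hippocampus count also ran from 0 to 14 over arrays left out. For the correlation of line differences 2 splits were as high, 0.0836 against a highest other of 0.0857, and a further one reached -0.0913, so that with a jackknife SE of 0.0529 the value is not clearly apart from 0. Chance may account for the 1 amygdala call (23 splits, highest other 5), the 4 amygdala lists (33, median of the others 3, highest 7) and the 5 hippocampus lists (5, median of the others 2, highest 6). The splits decide nothing for the 0 calls in the difference of the line effect between tissues (100, highest other 3) or the 0 probe sets called in both tissues (100, highest other 0). Any split reaches a count of 0.

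A first pattern is the same line difference in both tissues. The tables argue against a chance split: 1 of 100 splits gave as many as 72 probe sets, the highest other giving 10. With each amygdala array tied to its best-matching hippocampus array 1 of 100 splits reached 72, the highest other giving 24. This cannot decide whether the same animals sampled in both tissues are the cause, because it needs the ties to be the true animals. The ties were chosen from these data, and the weakest correlated at -0.138, 0.149 and 0.205. Wrong ties could lower the counts of the other splits. Linked genes carried along in each line may contribute, the 3 neighbouring pairs lying above what random sets give. Sequence differences under the probes stay open and cannot be told apart from a change in transcript level: the other probe sets of 34 genes had a median of 0.0773 in the same direction (95% bootstrap interval 0.0253 to 0.235; without probe sets that can share probes, 0.00706 to 0.122 in 31 genes), against 0.686 for the probe sets that named them, and selection and drift, which the design does not separate, stay untested.

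A second pattern is the choroid plexus signal. Choroid plexus tissue in some samples may account for it, since the other 18 markers (1 of the 19 in the list is also in another list) had a median correlation with Ttr of 0.793 in amygdala and 0.683 in hippocampus over 12 arrays. A line difference beside it stays open and cannot be told apart with 6 arrays per line: the group means of Ttr differed by 0.380 of the SD within lines in amygdala (95% bootstrap interval of high minus low -1.43 to 0.607) and 0.0568 in hippocampus (-1.05 to 0.986), the larger exact permutation p being 0.894, and those of the other markers by 0.514 and 0.154. The interval was added after the result was seen. How the tissue was dissected was not tested.

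The remaining pattern is that arrays of the tissues match under different numbers. In 34 genes that varied within groups in both tissues (SD above 0.35, mean above 8, choroid and meninges genes and genes that follow Ttr left out), amygdala array 1 and hippocampus array 2 correlated across genes at 0.740 and amygdala 6 and hippocampus 3 at 0.704, where arrays of different lines reached 0.329 at most. The weakest pairs of the best 1-to-1 matching within lines lay at -0.138, 0.149 and 0.205. Over all probe sets no pair of that matching lay above 0.0618, the highest value for arrays of different lines. There amygdala 1 with hippocampus 2 lay at 0.0606 and amygdala 6 with hippocampus 3 at 0.0534. Arrays of the same line under different numbers ran from -0.616 to 0.740, those of different lines from -0.366 to 0.329. The tables argue against the number as the mark of an animal, since the mean correlation of same-numbered arrays, -0.0701, lay at the 21.9th percentile of shuffled numbers. The same animals under different numbers may account for it: the best matching of arrays within lines had a mean correlation of 0.384, at the 99.95th percentile of 2000 shuffles made separately for each chromosome (median 0.271, highest 0.429). Matching across lines reached 0.174 and 0.191, a contrast that different animals sharing linked loci could also give. Littermates, or other variation shared by genes on different chromosomes, stay open and were not tested. The test by shuffles replaced an earlier form that had been run and that different animals sharing linked loci would also have passed.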
